A study of Homo sapiens with 9 samples.

How the data were processed

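Expression in 9 RNA samples of NCI-H716 cells was measured by the authors with an Illumina bead array, 3 arrays each for untreated cells, control vector and YAP mutant vector, taken as groups per the labels. RNA was isolated with a mirVana kit and amplified to biotin-labelled cRNA. The first deposited table, exported by the authors with BeadStudio (version not given in the sources used here), holds the probe intensity of 47230 probes per array, neither background-subtracted nor normalized between arrays and without detection p-values. The second deposited table holds log2 values that the authors quantile normalized without background correction; they differed by at most 0.005 from log2 quantile-normalized intensities computed here. All 9 columns were used, and 0 columns were left out. No pair of arrays held identical values (0 pairs).

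The intensities were background corrected with normexp (offset 50), quantile normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. The planned filter was a detection p under 0.05 on at least 3 of the 9 arrays. As the table holds no detection p, a probe was instead kept when its log2 signal on at least 3 arrays exceeded the mode of that array plus 1.645 times the SD of the lower side of the distribution, a change made on seeing the table. Of 463 olfactory receptor probes, which these cells should scarcely express, 5.2% to 6.5% lay above that floor, depending on the array. The filter kept 20218 probes. File symbols were updated with RefSeq (GRCh38.p14, names only): 27036 probes bore a current symbol, 4626 were updated through a synonym and 12244 kept the name of the file. Another 3270 probes had no name, and 54 bore a date in place of a symbol and were treated as unnamed. Each gene was represented by its brightest probe, which gave 15589 genes. Of the 53 genes called between the 2 vectors, 12 had more than 1 kept probe, with opposite signs in 1. A fold against a group in which a gene lay above background on no array is given as a lower bound against that floor.

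One limma model with a mean per group was fitted to all 9 arrays (6 residual degrees of freedom, 16.2 prior degrees of freedom), and the 3 comparisons between groups were tested with moderated statistics. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 15589 genes, and all tests were 2-sided. Errors beside log2 differences are standard errors from that model. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of 1 comparison, and again with an estimated correlation. The alternative list test, fry, asks whether a list changed at all, while camera sets it against the other genes. A list needed 5 tested members. The 25 lists, of which 24 could be tested, held 541 genes. They covered YAP/TAZ-TEAD targets, Hippo pathway components, the EGFR family, MAPK output, Wnt targets, enteroendocrine, intestinal, epithelial and mesenchymal genes, and actin and SRF targets. They also covered DNA replication, G2/M, p53 targets, apoptosis, interferon, NF-kappaB, unfolded protein response, heat shock, cholesterol synthesis, hypoxia and glycolysis, MYC targets and TGF-beta targets. Fibroblast, blood cell and endothelial markers stood for other cell types.

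The groups, comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. The rule named YAP1 and, between the vectors, the 12 largest rises and 12 largest falls among called genes with non-overlapping groups. In each of the other comparisons it named the 8 largest rises and falls, and per list up to 4 members with the smallest adjusted p between the vectors. CCN2, CCN1, ANKRD1, AREG, EREG, AXL, GCG and CHGA were named whatever their p, and probes without a symbol or with LOC or HS. names were passed over. Further called list members are named as examples against untreated cells, and a few genes that the rule or the lists name are counted but not reported here by name. Overlaps between comparisons that share arrays were set against 100 simulations of unchanged groups.

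The steps were tested on simulated data with known changes in 200 genes. Between the vectors, with 15083 simulated genes tested, 49.3% of changes of 0.5, 89.6% of changes of 1 and 89.4% of changes of 2 on the log2 scale were recovered, and 5.6% of calls were false. For the YAP mutant vector against untreated cells, with 15190 genes, the shares were 47.8%, 97.0% and 92.4%, with 4.8% false, and for the control vector against untreated cells, with 15135 genes, 49.3%, 88.1% and 92.4%, with 5.6% false. The simulated changes were added to raw log2 intensities, before background correction, and the noise was drawn independently for each probe. The shares therefore check the steps and do not measure recovery or false calls in real arrays, whose genes are correlated. Over all genes, replicate numbers paired the arrays weakly at most. Deviations from the group mean of equal numbers correlated at -0.198, -0.043 and -0.049 between untreated and control vector arrays. They correlated at 0.164, 0.013 and 0.077 between untreated and YAP mutant arrays and at -0.036, 0.093 and 0.081 between the vectors. Of 9 arrays, 4 correlated best with their own number. Some genes, such as ID3 and CYP1B1, were lowest in replicate 3 of both vector groups, while others, such as FOS, were not. The main fit had no block, a choice made beforehand because the replicate numbers say nothing of a shared day or culture. The files name no chip or hybridization date, so no chip effect could be fitted.

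Alternatives varied the background correction, normalization, filter, probe choice, variance prior, array weights, fitted samples, thresholds and list test, used the deposited log2 values, and left out each array in turn. A background from olfactory receptor probes, array brightness as a covariate, and leaving out both dim arrays (control vector replicate 3 and YAP mutant replicate 1) were added after the data were seen. As signal over background limits what an array can measure, differences in dim genes are compressed.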

Results

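Gene expression was measured with an Illumina bead array in NCI-H716, a human colorectal cancer cell line with enteroendocrine features. The 9 arrays fell into 3 groups of 3: untreated cells, cells with a control vector and cells with a vector for mutant YAP, the transcriptional coactivator at the end of the Hippo pathway. The labels do not say which mutation the YAP vector carries. Median raw signals ran from 104.2 in control vector replicate 3 and 104.6 in YAP mutant replicate 1 to 128.8 in untreated replicate 2, and 38.9% to 41.2% of probes lay above the background of their array. Log2 signals of replicates correlated across genes at 0.9938 to 0.9955, where genes are not independent replicates. On the first principal component, which held 31.1% of the variance, the untreated arrays lay between -15.35 and -13.34, the control vector arrays at 1.02, 1.85 and 9.31, and the arrays labelled YAP mutant between 6.89 and 13.49. Each group held 3 arrays, which limits the precision of every value below. Nothing says that the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

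YAP1 itself was measured by 1 probe, ILMN_1709479, and its signal was no higher in the arrays labelled YAP mutant. The log2 signals of YAP1 were 8.29, 8.17 and 8.01 in the untreated arrays, 7.85, 7.79 and 7.94 in the control vector arrays, and 8.06, 7.82 and 7.91 in the arrays labelled YAP mutant. The log2 difference of YAP1 was 0.07 ± 0.11 (SE, n = 3 per group) against the control vector (limma, adjusted p = 0.964). Against untreated cells YAP1 differed by -0.23 (adjusted p = 0.237), and the control vector differed from untreated cells by -0.30 (adjusted p = 0.163). The sources used here do not give the part of the transcript that the probe reads, so the YAP1 probe checks nothing about the labels. The groups are therefore named below as labelled.

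The comparison of the YAP mutant vector with the control vector asks which genes the YAP mutant changes beyond the effect of carrying a vector. RHBDF1, an inactive member of the rhomboid protease family that acts in the secretion of EGFR ligands, was 4.57-fold higher in the arrays labelled YAP mutant (log2 2.19 ± 0.11, SE, n = 3 per group; limma, adjusted p = 4.22e-11). CCN2, the connective tissue growth factor and a well-known YAP target, was 4.36-fold higher (log2 2.12 ± 0.14, adjusted p = 2.09e-09), and a second CCN2 probe differed by 1.41. KRT4, a keratin of stratified mucosal epithelia, rose by 1.52 ± 0.18 on the log2 scale (adjusted p = 6.52e-05). MYOF, a ferlin of membrane repair, rose by 1.38 ± 0.12 (adjusted p = 2.71e-07). FOS, an immediate early component of the AP-1 transcription factor, fell by 0.79 ± 0.13 (adjusted p = 0.00243). Its log2 signal was 7.15 to 7.39 in the arrays labelled YAP mutant, 7.82 to 8.34 in the control vector arrays and 6.77 to 7.08 in the untreated arrays. The fall of FOS is thus relative to control vector arrays that lay above the untreated ones.

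CGN, which encodes the tight junction protein cingulin, rose by 0.98 ± 0.11 on the log2 scale (limma, adjusted p = 3.11e-05). MSLN, a cell-surface glycoprotein common on mesothelium and carcinomas, was above background on 3 of 3 arrays labelled YAP mutant and on 0 of 3 control vector arrays, which made it at least 1.91-fold higher (adjusted p = 3.11e-05). KRT80, an epithelial keratin, was likewise above background on 0 of 3 control vector arrays and was at least 1.33-fold higher (adjusted p = 0.00192). MSLN and KRT80 missed the filter, and so were not tested, in some fits that left out arrays. VIPR1, a receptor for vasoactive intestinal peptide, rose by 0.98 ± 0.18 (adjusted p = 0.00776). BCL2L1, which encodes the anti-apoptotic protein BCL-XL, rose by 0.84 ± 0.10 (adjusted p = 9.72e-05), with 0.28 at a dimmer second probe. TAX1BP3, a small PDZ protein, rose by 0.84 (adjusted p = 0.00125), and AJUBA, a LIM protein that binds LATS kinases, rose by 0.79 (adjusted p = 0.00125). C1orf105, above background on 1 of 3 control vector arrays, differed by 0.75 (adjusted p = 0.00156). SSBP4, a single-stranded DNA binding protein, fell by 0.52 ± 0.10 (adjusted p = 0.0115). The calls of VIPR1, TAX1BP3, FOS and SSBP4 ended with arrays scaled to a common median and with a background set from olfactory receptor probes. Those of C1orf105 and VIPR1 ended without both dim arrays. VIPR1 lost its call with a prior variance that follows intensity and is robust to outliers, and SSBP4 with the mean over probes. VIPR1 also lost its call without control vector replicate 3 (0.0655) or YAP mutant replicate 2 (0.0758; 0.001 to 0.267 over all alternatives), and SSBP4 without control vector replicate 1 (0.0659) or 2 (0.0733) or YAP mutant replicate 2 (0.0599) or 3 (0.0616; 0.00345 to 0.713 over all alternatives).

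In total, 53 of 15589 genes passed the test, of which 50 were higher and 3 lower. By the fitted difference 5 of them differed at least 2-fold, among them MSLN, whose lower bound is 1.91-fold. The third lower gene, LOC731658, lay outside the naming rule and was looked up after its value was seen (log2 -0.55, adjusted p = 0.0375). All 53 genes had all 3 arrays of one group above all 3 of the other; chance gives this for 10% of unselected genes, but called genes are selected for such a difference. In all, 1012 genes had an unadjusted p under 0.05. Leaving out YAP mutant replicate 2 left 23 calls, control vector replicate 2 left 27, YAP mutant replicate 1 left 31 and control vector replicate 3 left 35, while scaling each array to a common median left 10 and a background set from olfactory receptor probes left 16. The 7 genes RHBDF1, CCN2, KRT4, MYOF, CGN, BCL2L1 and AJUBA were called without each array in turn and under each scaling, background, brightness and block alternative.

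**Figure D1:**
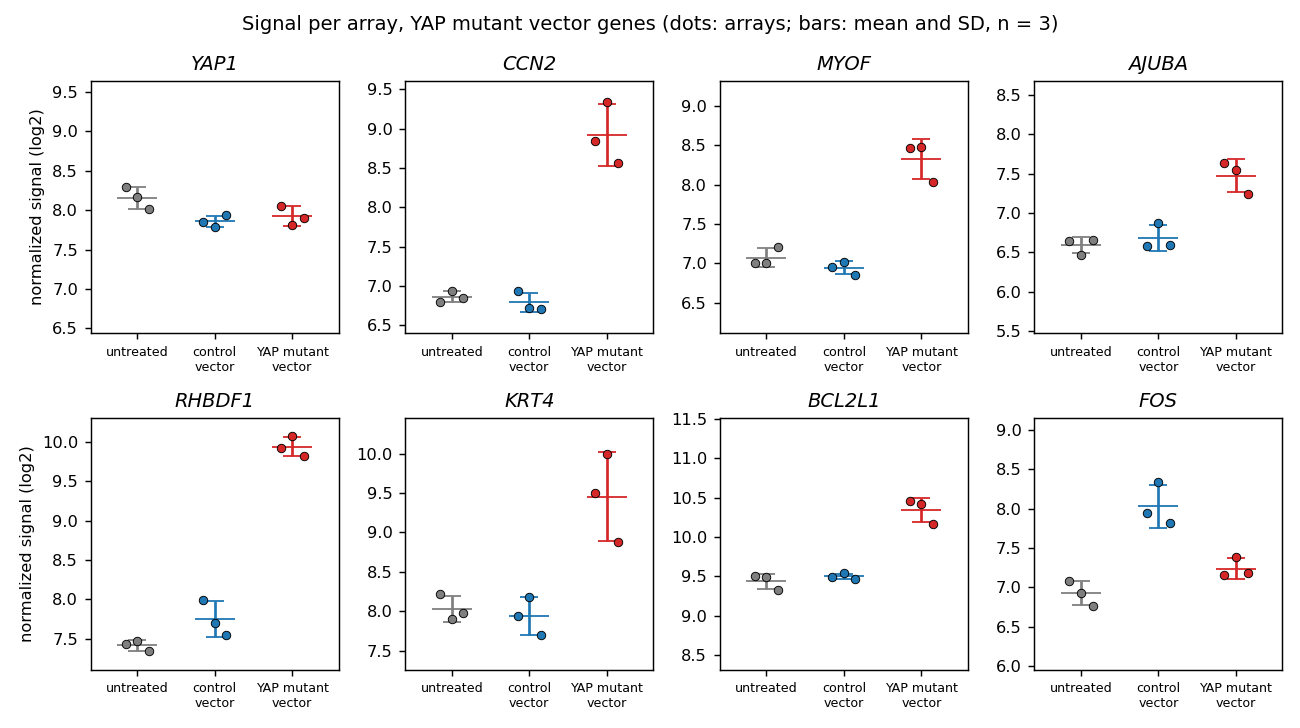
Log2 signal per array (points) and group mean with SD (bars) of YAP1 and of genes called between the arrays labelled YAP mutant and the control vector arrays, by group. CCN2 lay at 8.57 to 9.34 in the arrays labelled YAP mutant and at 6.72 to 6.94 in the other 6 arrays, while YAP1 lay at 7.82 to 8.06 in the arrays labelled YAP mutant and at 7.79 to 8.29 in the others.

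Among the gene lists, YAP/TAZ-TEAD target genes were higher in the arrays labelled YAP mutant than in the control vector arrays. Of 16 measured targets, 3 rose, namely CCN2, MYOF and AJUBA, and 4 did so when adjusted over the list alone. The set was shifted upward with a median log2 difference of 0.09 (camera, adjusted p = 2.26e-07; adjusted p = 0.064 with an estimated correlation). CCN1, another matricellular YAP target, differed by 0.38 ± 0.11 (adjusted p = 0.274). ANKRD1, AREG and AXL lay below the background filter, and the EGFR ligand EREG differed by 0.04. The kinases, adaptors and TEAD factors of the Hippo pathway gave 0 of 24 members past the test, with a median of -0.01 (adjusted p = 0.928).

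Of 23 measured genes of the actin cytoskeleton and SRF targets, 4 rose and 7 did so when adjusted over the list alone. As a set they were shifted upward, with a median log2 difference of 0.13 and 16 of 23 members above 0 (camera, adjusted p = 2.26e-07; adjusted p = 0.0619 with an estimated correlation). The actin-binding calponins CNN2 and CNN3 rose by 0.72 ± 0.10 (limma, adjusted p = 8.12e-04) and 0.55 ± 0.11 (adjusted p = 0.0183). The actin-binding protein TAGLN rose by 0.53 (adjusted p = 0.0336). CNN3 lost its call without control vector replicate 1 (adjusted p = 0.0659) or 3 (0.135), or without YAP mutant replicate 1 (0.0716) or 2 (0.203). TAGLN lost its call without each control vector array (0.0659, 0.121 and 0.166) and without YAP mutant replicate 1 (0.0982) or 2 (0.305). Over all alternatives their adjusted p ran from 0.00731 to 1 for CNN3 and 0.0224 to 1 for TAGLN, and the call of CNN2 ended with arrays scaled to a common median (adjusted p = 0.254; 1.82e-04 at the lowest).

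Intestinal absorptive and goblet genes were higher too, with 1 of 11 members past the test, 3 when adjusted over the list alone, and a median of 0.21 (camera, adjusted p = 3.48e-04; adjusted p = 0.0619 with an estimated correlation). GUCA2A, which encodes the gut peptide guanylin, rose by 0.58 ± 0.10 (limma, adjusted p = 0.00748), beside 0.31 for uroguanylin GUCA2B (adjusted p = 0.448) and 0.42 for the mucus protein FCGBP (adjusted p = 0.454). Epithelial junction and keratin genes gave 0 of 11 members past the test, 3 when adjusted over the list alone, and a set shift upward (adjusted p = 0.0238; adjusted p = 0.123 with an estimated correlation). Members with the smallest p were ELF3, an epithelial transcription factor, at 0.40, the plakoglobin gene JUP at 0.45 and KRT8 at 0.48. The EGFR family list was shifted upward (adjusted p = 0.0385; adjusted p = 0.149 with an estimated correlation), with the receptor ERBB2 up by 0.66 ± 0.11 (adjusted p = 0.00306) as 1 of 7 members past the test, also when adjusted over the list alone, and EGFR at 0.26 (adjusted p = 0.689). The call of the EGFR family list ended without control vector replicate 1 (adjusted p = 0.0946), 2 (0.139) or 3 (0.0502) and without YAP mutant replicate 1 (0.0737), 2 (0.15) or 3 (0.0508), with 0.0123 to 0.15 over all alternatives. That of the epithelial list ended without control vector replicate 2 (0.139) or YAP mutant replicate 1 (0.0565), with 0.00987 to 0.139 over all alternatives. Both ended without both dim arrays (0.0791 each), and the EGFR family call also with fry (0.0587) and without a filter on dim probes (0.137). KRT8 passed the test without YAP mutant replicate 3 (0.0202), and arrays scaled to a common median ended the calls of GUCA2A and ERBB2 (adjusted p = 1 and 0.252).

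MYC target and ribosome biogenesis genes were lower as a set in the arrays labelled YAP mutant, with 0 of 21 members past the test, 0 when adjusted over the list alone, and a median of -0.09 (camera, adjusted p = 0.00291; adjusted p = 0.123 with an estimated correlation). Examples were the nucleolar proteins NOLC1 and NOP58, both at -0.24, and BOP1 at -0.21. The p53 target genes were lower as a set as well, with 0 of 18 members past the test, 0 when adjusted over the list alone, and a median of -0.08 (adjusted p = 0.0467; adjusted p = 0.192 with an estimated correlation). The p53 call ended without control vector replicate 2 (adjusted p = 0.187) or 3 (0.164) and without YAP mutant replicate 1 (0.138) or 2 (0.165), with 0.00989 to 0.306 over all alternatives. The MYC call ended without YAP mutant replicate 3 (0.0908), with 1.69e-04 to 0.123 over all alternatives. With fry both ended (0.19 for p53 and 0.0992 for MYC), and the p53 call also without both dim arrays (0.306), with cyclic loess (0.0536), with arrays scaled to a common median (0.07), without a filter on dim probes (0.291) or with a stricter one (0.0587), and with the mean over probes (0.0516).

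The other 17 lists did not pass the test in this comparison, with adjusted p from 0.0682 to 0.928. Enteroendocrine genes had a median of -0.03 (camera, adjusted p = 0.0682), with the glucagon gene GCG at 0.00 ± 0.11, chromogranin CHGA at -0.07 ± 0.11 and secretogranin SCG2 at -0.44 ± 0.10 (limma, adjusted p = 0.0583). MAPK output genes (adjusted p = 0.812) held 1 member past the test, FOS, and 2 when adjusted over the list alone, with EGR1 at -0.42 (adjusted p = 0.28). Medians were 0.08 for Wnt targets, 0.05 for interferon response genes, 0.05 for unfolded protein response genes, -0.10 for heat shock genes, -0.05 for cholesterol synthesis genes, 0.02 for hypoxia and glycolysis genes, 0.01 for apoptosis regulators and -0.03 for TGF-beta targets. DNA replication genes, G2/M genes, mesenchymal transition genes and NF-kappaB genes had medians of 0.003, -0.01, -0.02 and -0.02. Of the markers of other cell types, fibroblast markers had a median of 0.00 (adjusted p = 0.638), although S100A4, which many other cells express, rose by 0.63 (adjusted p = 0.00748; 0.00128 to 0.588 over all alternatives). S100A4 lost its call without control vector replicate 2 (0.0733) or YAP mutant replicate 1 (0.0694) or 2 (0.0772). Blood cell markers had a median of -0.08 (adjusted p = 0.0682), and the endothelial marker ESAM, the only measured one, differed by 0.23 (adjusted p = 0.76). Enteroendocrine genes passed the test as lower without control vector replicate 1 (0.0163) or YAP mutant replicate 3 (0.041), interferon genes as higher without untreated replicate 3 (0.0295) or YAP mutant replicate 2 (0.0486), and blood cell markers as lower without control vector replicate 3 (0.0321) or YAP mutant replicate 2 (0.0486). Median, mean and test differed in sign for 7 lists here, namely Hippo, MAPK, mesenchymal, DNA replication, G2/M, NF-kappaB and TGF-beta, all without a call.

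**Figure D2:**
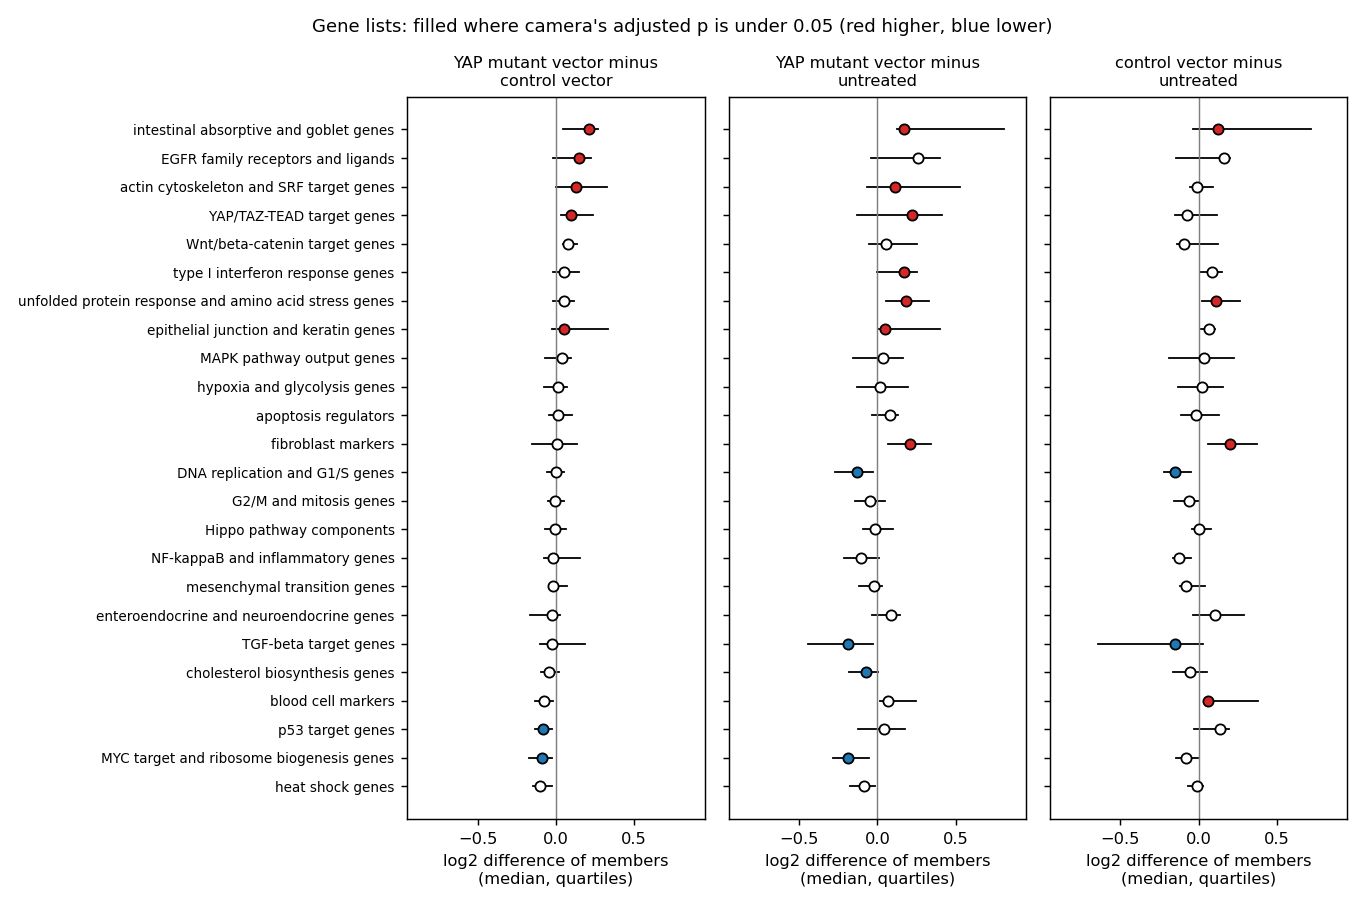
Median log2 difference of each gene list (horizontal axis) in the 3 comparisons, with the quartiles of its members as bars and filled points for lists with a camera adjusted p under 0.05. Intestinal absorptive and goblet genes lay above 0 in all 3 comparisons, with medians of 0.21, 0.17 and 0.12.

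Comparing the YAP mutant vector with untreated cells asks what the YAP mutant and its vector changed together. RHBDF1 was 5.76-fold higher in the arrays labelled YAP mutant (log2 2.53 ± 0.11, SE, n = 3 per group; limma, adjusted p = 2.15e-12), and CCN2 was 4.14-fold higher (log2 2.05 ± 0.14, adjusted p = 2.87e-09). GUCA2A was 2.99-fold higher (log2 1.58 ± 0.10, adjusted p = 2.15e-09), FCGBP rose by 1.43 ± 0.14 on the log2 scale (adjusted p = 1.04e-06), and the cholesterol exporter ABCA1 rose by 1.41 ± 0.17 (adjusted p = 1.22e-05). KRT4 and CGN both rose by 1.42. FANCA, a DNA repair gene, rose by 1.44 (adjusted p = 3.9e-07) at its brightest probe, whereas another FANCA probe differed by -0.22. The lowest values were those of ID3 and ID1, inhibitors of basic helix-loop-helix transcription factors, which fell by 1.70 ± 0.26 (adjusted p = 2.4e-04) and 1.34 ± 0.23 (adjusted p = 7.32e-04). CPNE4, a copine, fell by 1.17, WDR25 by 1.14, the cytochrome P450 gene CYP1B1 by 1.02, the LIM protein gene CRIP2 by 0.98 and SSBP4 by 0.87. The homeobox gene PRRX2 was 2.15-fold lower (adjusted p = 5.62e-07).

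Altogether 806 of 15589 genes passed the test against untreated cells, 524 higher and 282 lower, and 40 of them differed at least 2-fold. Of the 806, 800 had non-overlapping groups, where 10% is the chance share for unselected genes only, and 2864 genes had an unadjusted p under 0.05. Without YAP mutant replicate 3 the count was 475 and without untreated replicate 2 it was 499, while scaling to a common median left 182, the olfactory receptor background 452 and brightness as a covariate 516. ID3, ID1 and CYP1B1 lost their calls with a prior variance that follows intensity and is robust to outliers (adjusted p = 0.103, 0.125 and 0.0825, the highest over all alternatives, with 4.81e-07, 2.41e-05 and 3.04e-04 as the lowest), and CYP1B1 also with the olfactory receptor background (0.0608).

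Intestinal absorptive and goblet genes were the most clearly shifted list against untreated cells. Of 11 measured members, 5 rose, also when adjusted over the list alone, namely GUCA2A, FCGBP, GUCA2B (1.14), the trefoil peptide TFF3 (0.47) and the goblet transcription factor SPDEF (0.41), and the call held with an estimated correlation (camera, adjusted p = 1.22e-07; adjusted p = 0.0206 with an estimated correlation). Actin and SRF targets rose in 7 of 23 members, 8 when adjusted over the list alone, including TAGLN (0.77), TAGLN2 (0.74) and FHL2 (0.65). That set was shifted upward (camera, adjusted p = 2.56e-04, or 0.0998 with an estimated correlation), but its median of 0.11 was -0.05 with arrays scaled to a common median. The median of all genes was -0.08 under that scaling, and the call of the set held. YAP/TAZ targets rose in 4 of 16 members, CCN2, MYOF (1.25), AJUBA (0.88) and GADD45A (0.80), and fell in 2, IGFBP3 (-0.85) and F3 (-0.60), with 5 and 3 when adjusted over the list alone (adjusted p = 0.00545; adjusted p = 0.17 with an estimated correlation). Epithelial junction genes rose in 3 of 11 members, 4 when adjusted over the list alone, namely JUP (0.97), ELF3 (0.62) and KRT8 (0.50) (adjusted p = 0.0123; adjusted p = 0.0998 with an estimated correlation).

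Stress and interferon lists were also higher against untreated cells. Unfolded protein response and amino acid stress genes rose in 3 of 20 members, 6 when adjusted over the list alone, namely DDIT4 (0.63), PHGDH (0.50) and ASNS (0.47), which are a stress-induced mTOR inhibitor and enzymes of serine and asparagine synthesis rather than chaperones (camera, adjusted p = 6.27e-04; adjusted p = 0.17 with an estimated correlation). Interferon response genes rose in 2 of 14 members, 3 when adjusted over the list alone, IFI6 (0.96) and STAT2 (0.36) (adjusted p = 0.0101; adjusted p = 0.0998 with an estimated correlation). Fibroblast markers moved with these groups, with 2 of 8 members higher, also when adjusted over the list alone, S100A4 (0.92) and lumican LUM (0.51) (adjusted p = 0.0114; adjusted p = 0.0998 with an estimated correlation). The fibroblast call ended without untreated replicate 2 (adjusted p = 0.0684; 0.00387 to 0.0998 over all alternatives) and with brightness as a covariate (0.0752), and the interferon call ended without a filter on dim probes (0.0847).

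MYC, DNA replication, TGF-beta and cholesterol lists were lower against untreated cells. MYC and ribosome biogenesis genes had 1 of 21 members lower, NOP56 (-0.42), and 5 when adjusted over the list alone (camera, adjusted p = 6.27e-04; adjusted p = 0.0998 with an estimated correlation). DNA replication genes had 2 of 26 lower, CCNE1 (-0.52) and RRM2 (-0.43), and 4 when adjusted over the list alone (camera, adjusted p = 0.00123, or 0.118 with an estimated correlation). The value of CCNE1 is that of its brightest probe, and its other kept probes differed by only -0.120, -0.114 and -0.095. Of 12 TGF-beta targets, ID1, ID3 and ID2 (-0.83), which BMP signals also induce, fell and the receptor TGFBR2 (0.57) rose, with 6 lower and 2 higher when adjusted over the list alone (adjusted p = 0.0136; adjusted p = 0.118 with an estimated correlation). Cholesterol synthesis genes had 2 of 23 lower, also when adjusted over the list alone, among them the squalene epoxidase gene SQLE (-0.37) (adjusted p = 0.0326; adjusted p = 0.17 with an estimated correlation). The cholesterol call ended without untreated replicate 1 (adjusted p = 0.0564) or YAP mutant replicate 2 (0.151), with 0.00431 to 0.17 over all alternatives. The cholesterol and TGF-beta calls ended with the olfactory receptor background (0.0629 each), and the TGF-beta call without a filter on dim probes (0.0806). The remaining 13 lists had camera adjusted p from 0.0867 to 0.952, and heat shock genes passed as lower without untreated replicate 2 (0.047). With fry, EGFR family (adjusted p = 0.0182), hypoxia and glycolysis (0.0185) and apoptosis genes (0.0439) passed as higher. NF-kappaB and heat shock genes passed as lower with fry (0.0306 each). The Hippo and p53 lists, both without a call, differed in sign between median, mean or test. Of 20 enteroendocrine genes, SCG2 (-0.87) and the prohormone convertase PCSK1 (-0.57) fell and the granins SCG3 (0.43) and SCG5 (0.34) rose, with a median of 0.09 (adjusted p = 0.611).

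Genes called against both control groups were compared next, to see which effects of the YAP mutant vector held against either. Both comparisons called 45 genes the same way, 44 higher and 1 lower, among them RHBDF1, CCN2, KRT4, MYOF, CGN, BCL2L1 (0.84 and 0.90) and ERBB2 (0.66 and 0.60). Independent lists would share 1.68 higher and 0.0543 lower genes. Both comparisons use the same 3 arrays labelled YAP mutant. Simulations of unchanged groups that share those arrays gave 0.02 shared calls on average and at most 1. These simulations hold no group effect, so few shared calls follow by construction. They cannot tell how many shared calls the common arrays add once groups differ. Across genes, which are not independent replicates, the log2 differences correlated at 0.549, against 0.499 in the simulations, and their covariance exceeded the simulated one by 0.00821. The 3 shared arrays were too few to divide, so part of the excess may come from them. Without YAP mutant replicate 2, control vector replicate 2 or YAP mutant replicate 1, the shared calls numbered 21, 25 and 28, and they numbered 10 with arrays scaled to a common median, 16 with the olfactory receptor background and 26 without both dim arrays.

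The control vector was compared with untreated cells to measure what a vector without the YAP mutant changed. ABCA1 was 2.49-fold higher with the control vector (log2 1.32 ± 0.17, SE, n = 3 per group; limma, adjusted p = 1.41e-04), and BEX2, a brain-expressed X-linked family gene, rose by 1.12 ± 0.10 on the log2 scale (adjusted p = 2.32e-06). FOS rose by 1.11 ± 0.13 (adjusted p = 2.57e-05), while the arrays labelled YAP mutant differed from untreated cells by 0.32 (adjusted p = 0.161). The antigen-presenting molecule HLA-B rose by 1.07 ± 0.10 (adjusted p = 3.08e-06), the matrix protein gene SPON1 by 1.06, FCGBP and GUCA2A both by 1.00 and the rhomboid gene RHBDL3 by 0.95. ID3 fell by 1.59 ± 0.26 (adjusted p = 0.00137) and ID1 fell by 1.24 ± 0.23 (adjusted p = 0.00393). CPNE4 fell by 1.09, WDR25 by 1.04, CYP1B1 by 1.00, PRRX2 by 0.98, the BMP and Wnt antagonist SOSTDC1 by 0.96 and IGFBP3, above background on 2 of 3 control vector arrays, by 0.95.

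In all, 340 of 15589 genes passed the test between control vector and untreated cells, 237 higher and 103 lower, with 12 at least 2-fold different and 339 with non-overlapping groups. The share of higher genes was 69.7%, and 59.6% with arrays scaled to a common median. An unadjusted p under 0.05 was found for 2170 genes. The count was 157 without control vector replicate 3, 182, 184 and 198 without untreated replicates 1, 2 and 3, 47 with arrays scaled to a common median, 119 with the olfactory receptor background, 188 with brightness as a covariate and 159 without both dim arrays. ID3, ID1 and CYP1B1 lost their calls with the robust intensity-dependent prior (adjusted p = 0.183, 0.222 and 0.134, the highest over all alternatives, with 4.6e-06, 1.85e-04 and 8.21e-04 as the lowest) and with the olfactory receptor background (0.079, 0.109 and 0.11).

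Of 11 intestinal genes, GUCA2A, FCGBP, GUCA2B (0.84) and TFF3 (0.60) rose with the control vector, 4 in all and 4 when adjusted over the list alone (camera, adjusted p = 6.6e-05; adjusted p = 0.0638 with an estimated correlation). TGF-beta targets fell in 4 of 12 members, 5 lower and 1 higher when adjusted over the list alone, namely ID1, ID3, ID2 (-0.76) and the BMP-induced inhibitor SMAD6 (-0.60) (adjusted p = 0.00366; adjusted p = 0.139 with an estimated correlation). DNA replication genes were lower as a set with 0 of 26 members past the test, 0 when adjusted over the list alone, and a median of -0.15 (adjusted p = 3.45e-04; adjusted p = 0.139 with an estimated correlation). Unfolded protein response and amino acid stress genes were higher with 1 of 20 members past the test, DDIT4 (0.61), and 2 when adjusted over the list alone (adjusted p = 0.00366; adjusted p = 0.317 with an estimated correlation). Fibroblast markers were higher as a set with 0 of 8 members past the test and 4 when adjusted over the list alone (adjusted p = 0.0149; adjusted p = 0.139 with an estimated correlation). Blood cell markers rose in 2 of 7 members, CD14 (0.43) and the globin HBB (0.45), and 3 when adjusted over the list alone (adjusted p = 0.0452; adjusted p = 0.23 with an estimated correlation). With fry in place of camera only the intestinal call held, and those of the TGF-beta, DNA replication, stress, fibroblast and blood cell lists ended (adjusted p = 0.0598, 0.0598, 0.0793, 0.0598 and 0.0617). The TGF-beta, fibroblast and blood cell calls also ended with the olfactory receptor background (0.0595 each), and the fibroblast call with brightness as a covariate (0.107). The blood cell call ended without untreated replicate 1 (adjusted p = 0.149), control vector replicate 1 (0.142) or control vector replicate 2 (0.0745), with 0.0108 to 0.23 over all alternatives. The remaining 18 lists had adjusted p from 0.103 to 0.953, YAP/TAZ targets among them (median -0.08, adjusted p = 0.457). Enteroendocrine genes passed as higher without control vector replicate 1 (0.0427), and 4 uncalled lists (Hippo, Wnt, actin and apoptosis) differed in sign between median, mean or test.

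**Figure D3:**
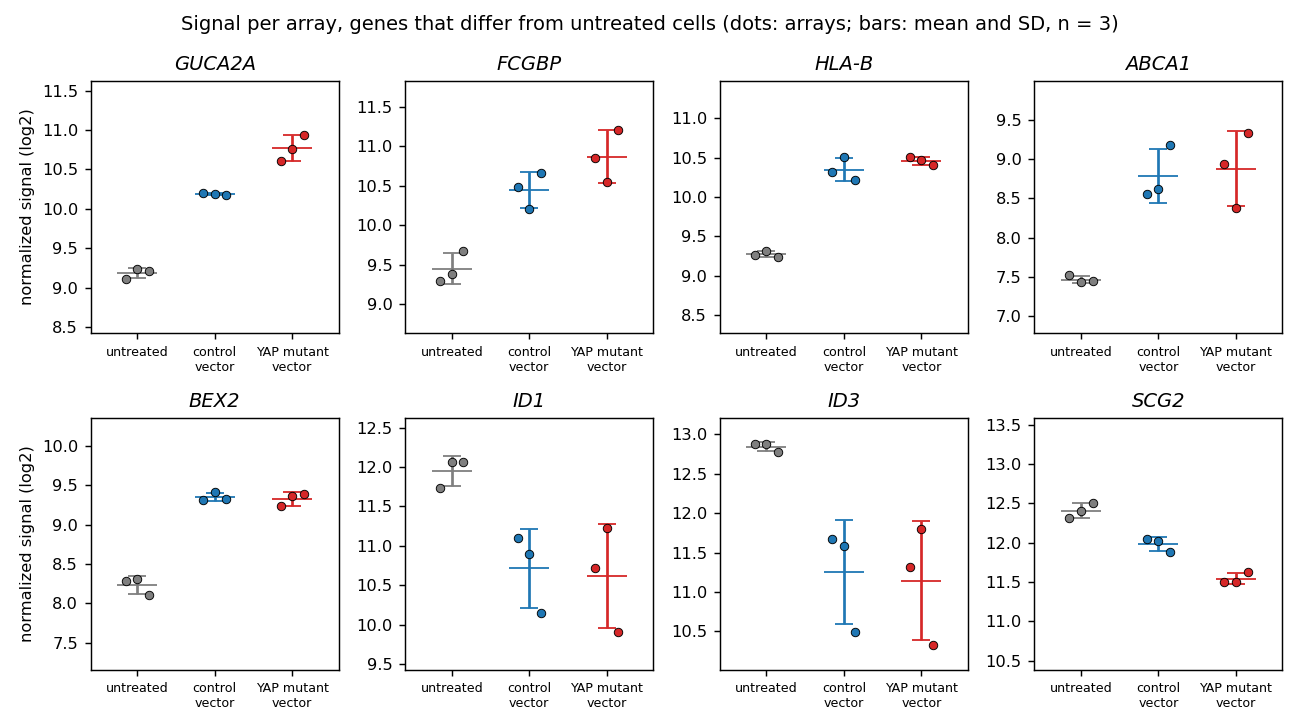
Log2 signal per array (points) and group mean with SD (bars) of genes called between control vector and untreated cells, by group. ID3 lay at 12.78 to 12.88 in the untreated arrays and at 10.32 to 11.80 in the 6 vector arrays, with the lowest value of each vector group in replicate 3.

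Of the 340 genes called between control vector and untreated cells, 261 were called the same way between the arrays labelled YAP mutant and untreated cells, 196 higher and 65 lower, including ABCA1, GUCA2A, FCGBP, ID1, ID3 and CPNE4. Independent lists would share 7.97 higher and 1.86 lower genes. Simulations of unchanged groups that share the untreated arrays gave 0.04 on average and at most 2, few by construction. They cannot tell how many shared calls the untreated arrays add once groups differ. The covariance exceeded the simulated one by 0.01923. From control vector to YAP mutant, 12 of the genes that moved from untreated to control vector were called again. GUCA2A, CGN, CAVIN2, ARHGAP23, CAPN2, GPBAR1, MS4A8 and VAMP5 rose in both steps, and FOS rose in the first and fell in the second, as did LOC731658, while LOC728416 and LOC729255 fell and then rose. These genes were named after their values were seen, and independent lists would share 0.76 higher and 0.0198 lower genes. Both steps use the control vector arrays with opposite sign, which by itself gave a correlation across genes of -0.501 in simulations of unchanged groups, against the observed -0.13. Group differences widen both shifts and draw such a correlation toward 0 even where the shifts are unrelated. The gap between these correlations therefore does not show that the steps run together. The covariance was -0.00288, against a simulated -0.00625.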

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

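The olfactory receptor background, the brightness covariate and leaving out both dim arrays were chosen after the data were seen; the other alternatives were planned, and normexp with an offset of 50 was the setting used throughout. Counts are given for YAP mutant against control vector, YAP mutant against untreated, control vector against untreated, and genes called the same way against both control groups. A chip block was not run, as the files name no chip. No gene or list reversed by its test. The median of the actin list against untreated cells turned to -0.05 under median scaling, where the median of all genes was -0.08. Scaling to a common median gave 10, 182, 47 and 10 genes, an adjusted p under 0.01 gave 27, 389, 138 and 25, a 2-fold minimum gave 5, 40, 12 and 5, and treat against a fold of 1.2 gave 7, 117, 29 and 7; a stricter threshold lowers a count by construction, and the cause was not tested for the scaling. The olfactory receptor background gave 16, 452, 119 and 16 genes and 3 lists for control vector against untreated. The brightness covariate gave 516 and 188 genes in the comparisons with untreated cells. Without both dim arrays there were 27 genes and 4 lists between the vectors, 159 genes for control vector against untreated and 26 shared genes, with fewer arrays in the fit. The cause was not tested for the background or the covariate. With an estimated correlation 0, 1 and 0 lists were called, and fry called 4, 16 and 1, against 7, 11 and 6 with camera. The replicate block gave 64, 868, 383 and 53. Leaving out single arrays gave 23 to 54, 475 to 874, 157 to 371 and 21 to 45 genes and 4 to 8 lists between the vectors, the 4 without control vector replicate 2 or without YAP mutant replicate 1. Of the calls between the vectors, 20 of 53 were made whichever array was left out, as were 316 of 806 and 112 of 340 in the others, and 7, 160 and 42 also held under each scaling, background, brightness and block alternative. The YAP1 probe differed by 0.004 to 0.125 over all alternatives, none past the test. Among named genes called, 448 values kept and 23 lost the call when an array was left out, and 700 kept and 40 lost it under other alternatives. MSLN and KRT80 were tested under only 19 alternatives, against 23 for genes such as CCN2. Where they missed the filter they count as neither kept nor lost. CNN3, TAGLN, S100A4, SSBP4, VIPR1 and GUCA2A lost calls under both median scaling and the olfactory receptor background, as did TAX1BP3 and FOS. ERBB2 and CNN2 lost theirs under median scaling, and C1orf105 lost its call without both dim arrays, as did CNN3, TAGLN, S100A4 and VIPR1. SCG2 and IFI6, not called between the vectors, passed in 10 cases, among them with the deposited log2 values (adjusted p = 0.0156 and 0.0236). Called lists kept 197 and lost 19 calls without single arrays, and kept 331 and lost 52 otherwise. The median of all genes moved by less than 0.1 under each scaling.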

Other observations

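The gene groups in the first paragraphs were put together after the values were seen, so no set test is given for them. The tests by rotation of residuals, of exchanged labels and of array brightness were also chosen then. The single-array test was written before it was run, but with the pattern that it tests already known. The splits as a test of chance and the probe-position test were planned. Of 16 measured HLA class I and antigen processing genes, 7 rose with the control vector against untreated cells (limma). The classical molecule HLA-B rose by 1.07 on the log2 scale (adjusted p = 3.08e-06), HLA-F, HLA-G and HLA-E by 0.80, 0.59 and 0.53, and the peptide transporter subunit TAP1 by 0.41 (adjusted p = 0.0484), while B2M, the light chain, differed by 0.28 (adjusted p = 0.226). Against untreated cells the arrays labelled YAP mutant gave 8 of the 16 higher, with HLA-B at 1.19 (adjusted p = 1.8e-07). Between the vectors 0 of 16 passed, where HLA-B differed 1.08-fold (adjusted p = 0.928) and HLA-E by 0.44 (adjusted p = 0.102). Of 9 measured genes that the sterol receptor LXR induces, the exporters ABCA1 and ABCG1 rose with the control vector, by 1.32 (adjusted p = 1.41e-04) and 0.81 (adjusted p = 3.17e-04), and 7 did not pass, among them SREBF1 at 0.12 and FASN at 0.20.

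ID1, ID2 and ID3, the 3 measured ID genes, fell with the control vector by 1.24, 0.76 and 1.59 (limma, adjusted p = 0.00393, 0.00892 and 0.00137). Their signal was uneven within groups, as ID3 was 11.68, 11.59 and 10.49 in control vector replicates 1 to 3 and 11.31, 11.80 and 10.32 in those labelled YAP mutant, against 12.78 to 12.88 in untreated arrays, and the calls of ID1 and ID3 ended with a robust prior variance and with the olfactory receptor background. Of 10 measured immediate early genes, FOS (1.11) and FOSB (0.43, adjusted p = 0.025) rose with the control vector. Between the vectors FOS was the 1 member past the test, at -0.79, and EGR1 was at -0.42 (adjusted p = 0.279). Of 6 measured caveola genes, the coat protein genes CAVIN1 and CAVIN2 rose between the vectors, by 0.58 (adjusted p = 0.0168) and 0.59 (adjusted p = 0.00457), while CAV1, at 0.07, and the other 3 did not pass.

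Relabelling the 6 arrays of a comparison gives 10 splits, which cannot give a share under 0.1. In each comparison 1 of 10 splits, the real one, gave as many calls. Between the vectors limma called 53 genes and camera 7 lists, and the highest of the other splits gave 2 genes and 4 lists. At an unadjusted p under 0.05 another split between the vectors gave 1100 genes, more than the 1012 of the real one. For the YAP mutant against untreated cells the counts were 806 genes and 11 lists, against at most 0 genes (up to 1040 at an unadjusted p under 0.05) and 4 lists, and for the control vector against untreated cells 340 genes and 6 lists, against at most 0 genes (up to 1361 at an unadjusted p under 0.05) and 1 list. For the 45 genes called the same way against both control groups, 2 of 100 splits of the 9 arrays, the real one included, gave as many. Most of these splits mixed arrays of groups that differ, which lowers their counts, so the share cannot decide whether chance gave the 45. The other 2 splits that kept the YAP mutant arrays as the shared group mixed untreated with control vector arrays and gave 25 and 34, so shared calls also arose with mixed control groups. The other split with as many gave 259 and compared the 3 untreated arrays, as the shared group, with mixed vector arrays, which points to a structure of the samples in which untreated arrays stand apart.

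The shift from control vector to YAP mutant arrays ran along the shift from untreated to control vector arrays more than shared arrays give, with a covariance across genes of -0.00288 against a simulated -0.00625, and of the genes called with the control vector, 161 of 237 higher ones and 39 of 103 lower ones kept their sign between the vectors, counts that the shared arrays lower and for which no value without change was computed. With brightness as a covariate the covariance was -0.00243, above simulations of -0.00608 to -0.00538, and its excess over the simulated mean was 0.00327. The excess was 0.00337 without the covariate, so a linear effect of brightness took up little of it. These simulations drew each gene independently, and none that keeps the correlations between genes was run with the covariate. Brightness is therefore not excluded. With all arrays, 0 of 100 rotations of the residuals gave a covariance as high as the observed one (-0.0107 to -0.00376). Without control vector replicate 1 the observed covariance was -0.00854, against a simulated mean of -0.00928, and no rotations were run without that array. The rotations therefore cannot decide on the same effect of both vectors, with nothing graded between them, which stays open. A single deviating array also stays open. The excess over the simulated covariance dropped from 0.00337 to 0.000736 without control vector replicate 1, and to 0.00128 without YAP mutant replicate 3. The first of these values lay under a bound of 0.001, which was written before this test but with the full excess already known. A graded response of the cells, from a longer or stronger exposure to a vector or from YAP, may account for it and was not tested.

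The YAP1 probe was no higher in the arrays labelled YAP mutant, at a log2 difference of 0.07. An array labelled YAP mutant exchanged with an untreated array is argued against, because the 9 splits that exchange arrays gave at most 0 calls and 1040 genes with an unadjusted p under 0.05, against 806 and 2864 as labelled. An exchange with a control vector array is argued against by CCN2, a target named before the data were seen, which lay at 8.57 to 9.34 in all 3 arrays labelled YAP mutant and no higher than 6.94 in the others (a gap of 1.62, residual SD 0.17), although 1 split with such an exchange gave 1100 genes with an unadjusted p under 0.05 against 1012. Although CCN2 was named beforehand, both tests of exchanged labels were chosen with these values already known. A probe outside the part of YAP1 that the vector carries, such as one in an untranslated region, may account for the value and stays open at 0.07, because the position of the probe is not given in the sources used here. Low expression of the vector stays open too and was not tested.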
